A study of Mus musculus with 138 samples.

How the data were processed

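RNA was measured in striatum and cerebral cortex of 69 mice of C57BL/6 background, 1 library per tissue and mouse, 138 in all. The labels give 9 genotypes made from the heterozygous Q140 knock-in allele, the Rgs9Cre allele and the floxed Msh2 allele, and so 18 groups of 6 to 8 mice. Both tissues of a mouse were matched by the mouse label, whose first number, which mice can share, is the mouse number used below. The age label and the design text give 12 months, while the labels' extraction protocol speaks of striatal tissue at 6 months; 12 months is used here. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and libraries were made with the Illumina TruSeq stranded protocol. Genotypes of the samples were updated by the submitters, and the updated ones are used.

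The deposited table holds raw whole-number read counts per gene for 48795 genes with Ensembl identifiers. Per the submitters' processing notes, STAR 2.7.5c, SAMtools 1.10 and HTSeq 0.12.3 were used with GRCm38/mm10. The strand mode and the treatment of reads with several alignments are not given in the sources used here. A table of FPKM values of the same libraries was not used, since a count test fits the counts. All 138 count columns matched a library by its description, and 0 columns were left out. Positions and exon lengths came from GENCODE vM21 on the same build, in which 48435 of the 48795 identifiers (99.26%) were found, 48421 of them on the strand the table gives. Repeated gene names, 126 in all, were kept apart by their identifier.

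Each library holds 28.08 to 51.79 M counts (M, the mega prefix), so that a gene at 1 CPM, the count scaled to a library total of 1 M, has about 34 counts at the striatal median of 34.06 M. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Before averaging, all 2346 pairs of libraries of a tissue were compared by chi-square over genes with a total of at least 100 counts, and none agreed within sampling noise. Each library was also described by its share of mitochondrially encoded counts and by its length slope, the slope of its log2 CPM, relative to the mean of its tissue, on log2 exon length. Libraries over 3 robust SD from the median slope of their tissue were called extreme, a choice made after seeing the data.

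Comparisons between genotypes were fitted in R 4.3.3 with edgeR 4.0.16, per tissue, with all 9 genotypes in a single fit so that they share the estimate of spread. Genes were kept by filterByExpr (minimum count 10, minimum total 15, large group size 10, proportion 0.7), which left 19095 in striatum and 18840 in cortex. TMM factors, glmQLFit and glmQLFTest gave log2 fold changes, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with calls at an adjusted p under 0.05 and no minimum fold. SE values are those of the log2 fold change. There were 19 comparisons between genotypes, interactions included, and the difference of the Q140 effect between tissues was tested with the mouse as a block and an interaction of tissue and Q140. No covariate was used, since the labels state no model and the sex labels of striatal libraries do not all go with their RNA. P-values measure the spread between mice of a group.

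The text names Msh2, Htt and Rgs9 in the comparisons, then up to 10 genes per direction with the largest log2 fold change among those called with a mean log2 CPM of at least 1 (prior count 2), then up to 4 members with the smallest p of each list that passed. Xist and Y-linked genes are left out. Genes outside the rule are said to be chosen after their values were seen. This rule, the designs, the gene lists and 20 alternative settings were fixed before the data were examined, and 4 settings were added afterwards (without the libraries of extreme length slope, the length slope as a covariate, the mouse number of the labels as a covariate, and the 50 genes of largest change per direction as signature).

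The 29 gene lists hold projection neuron, interneuron, astrocyte, reactive astrocyte, microglia, disease-associated microglia, mature oligodendrocyte, oligodendrocyte precursor, endothelial and mural, choroid plexus and ependymal, fibroblast and meningeal, and blood cell genes, and cortical excitatory, thalamic and hypothalamic markers. Further lists hold immediate early genes, clustered protocadherins, Hox genes, developmental transcription factors, cholesterol biosynthesis, mismatch repair and CAG repeat instability, p53 and DNA damage response, interferon response, heat shock and chaperones, oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrially encoded genes, synaptic vesicle and release, glutamate receptors and postsynaptic density, and potassium channels. No Hox gene passed the filter in cortex, which left 28 lists there. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. A fold against a group at 0 was taken against a floor of 3 counts over the group.

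The signature score of a library is the mean log2 CPM of genes called higher in Q140 than in WT minus that of genes called lower, computed per tissue. The effect remaining with Rgs9Cre Msh2fl/fl is the carrier minus non-carrier difference with Rgs9Cre Msh2fl/fl as a percentage of that with Rgs9Cre. Its 95% interval came from 10000 bootstrap draws over mice, and its p from 100000 permutations. Differences of 2 group means were tested with exact permutation over all splits of the libraries, two-sided. Overlaps of calls were set against the number that independent lists would give, for comparisons that share no library.

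Alternatives changed 1 choice at a time. They were DESeq2 1.42.0, RLE size factors, no low-count filter, a stricter filter of 50 counts in 6 libraries, limma voom with quality weights, only the groups compared, sex label, Xist or the 9 plate columns as covariates, and the replicate number as a block. For the signature they were other gene choices, a prior count of 0.5 and another source comparison. Up to 100 splits of the libraries were refitted for each comparison. The scripts were tested on simulated counts with 200 changed genes. The simulated spread followed the expression level of a gene alone, without structure by length slope or mouse number, and changed genes lay above 2 CPM. Of 50 genes changed 1.25-fold in the striatal Q140 and WT groups, 30 were recovered, and all 50 of those changed 1.5-fold, 2-fold or 3-fold. Sequences of Gm6969 and Cox7a2l were aligned with blastn 2.17.0. Python 3.11.15 with matplotlib 3.10.9 drew the figures.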

Results

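The knock-in allele of Huntington's disease and the mismatch repair gene Msh2 were combined in mice, and RNA was measured in 2 brain regions of each animal. The Q140 allele carries an expanded CAG repeat in the mouse Htt gene and was present in 1 copy. Msh2 encodes a mismatch repair protein that is known to drive expansion of the CAG repeat in somatic cells. In these crosses its floxed allele was combined with Cre recombinase expressed from the Rgs9 locus, a gene of striatal projection neurons. Whole-tissue RNA-seq libraries were available from striatum and cerebral cortex of 69 mice, 138 libraries in all, labelled as 12 months old. The 9 genotypes gave 18 groups. Each group held 8 mice except WT with 7 and Rgs9Cre Msh2fl/fl with 6. Total counts per library, in M (the mega prefix), ran from 28.08 to 51.79 M, with a median of 34.06 M in striatum and 34.73 M in cortex. No pair of libraries of a tissue agreed within sampling noise, since the lowest chi-square per degree of freedom was 3.11 in striatum and 2.79 in cortex.

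The genes changed in the crosses were read first. Msh2 (ENSMUSG00000024151, chromosome 17, 87672330 to 87723713, GRCm38) was measured at 22.4 ± 1.04 CPM (counts scaled to a common library total of 1 M; SD, n = 7) in WT striatum. In Rgs9Cre Msh2fl/fl striatum it stood at 23.5 ± 1.65 CPM (n = 6), and in Q140 Rgs9Cre Msh2fl/fl striatum at 25.9 ± 0.814 CPM (n = 8), against 23.9 ± 1.02 CPM (n = 8) in Q140 Rgs9Cre. The labels do not say which part of Msh2 is flanked by the lox sites, so the level of the whole gene checks nothing about the deletion. Htt (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534) was at 207.6 ± 15.4 CPM (n = 8) in Q140 and 203.4 ± 35.3 CPM (n = 7) in WT striatum, with a log2 change of 0.03 ± 0.09 SE (edgeR adjusted p = 0.835). The direction turned in settings chosen after seeing the data. The log2 change of Htt was −0.07 without the libraries of extreme length slope (adjusted p = 0.455), −0.06 with the mouse number as a covariate (adjusted p = 0.6001) and −0.24 with the length slope as a covariate (adjusted p = 4.1e-06).

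Rgs9 (ENSMUSG00000020599, chromosome 11, 109225355 to 109298129), a regulator of G protein signalling in projection neurons and the locus that carries Cre, was lower in striatum with Q140 and with Cre. It fell from 880.9 ± 53.6 CPM (n = 7) in WT to 456.7 ± 37.1 CPM (n = 8) in Q140. Rgs9Cre striatum held 678.3 ± 42.7 CPM (n = 8) and Q140 Rgs9Cre 364.5 ± 53.8 CPM (n = 8). In cortex Rgs9 was far lower than in striatum, at 7.78 CPM in WT and 5.22 CPM in Rgs9Cre Msh2fl/fl.

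The sex labels of the striatal libraries did not all go with their RNA. Xist and the Y-linked genes went with the label in 69 of 69 cortical libraries but in 39 of 69 striatal ones, and the remaining 30 were 15 of each sex. RNA gave the same sex in both tissues of all 69 mice. Sex was therefore not a term of the fits, and library names below carry the labelled sex.

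Libraries also differed in how counts depended on gene length. In 9 striatal and 2 cortical libraries long genes were depleted against the other libraries of the tissue, by over 3 robust SD. The striatal ones were WT F2 and M4, Rgs9Cre F2, M2 and M3, Q140 Rgs9Cre F2, Q140 Rgs9Cre Msh2+/fl M2 and M4, and Rgs9Cre Msh2fl/fl M2, and the cortical ones were Rgs9Cre F3 and M2. The share of counts from mitochondrially encoded genes was 12.58% in Q140 Rgs9Cre Msh2+/fl M2, where the mean of all striatal groups lay between 5.67% and 6.82%. The slope averaged −0.03 in WT, −0.02 in Rgs9Cre and −0.01 in Q140 Rgs9Cre striatum, and 0.02 in Msh2fl/fl, Q140 and Q140 Rgs9Cre Msh2fl/fl striatum. The 9 striatal libraries came from mice with low numbers in their labels, 8 of them between 3 and 12 and 1 at 23, where 19 of the 69 mice had a number of 12 or lower. This is the first number of the mouse label, which mice can share, and the labels do not say what it stands for. Its median was 7.5 in Rgs9Cre, 15 in WT, 19 in Q140 Rgs9Cre, 28.5 in Q140 and 44 in Msh2fl/fl mice, so comparisons between genotypes also compare mice of different numbers. With the number as a covariate, a setting chosen after seeing the data, the counts of genes for Q140 against WT below stayed within 1.5 times their value in both tissues.

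**Figure D1:**
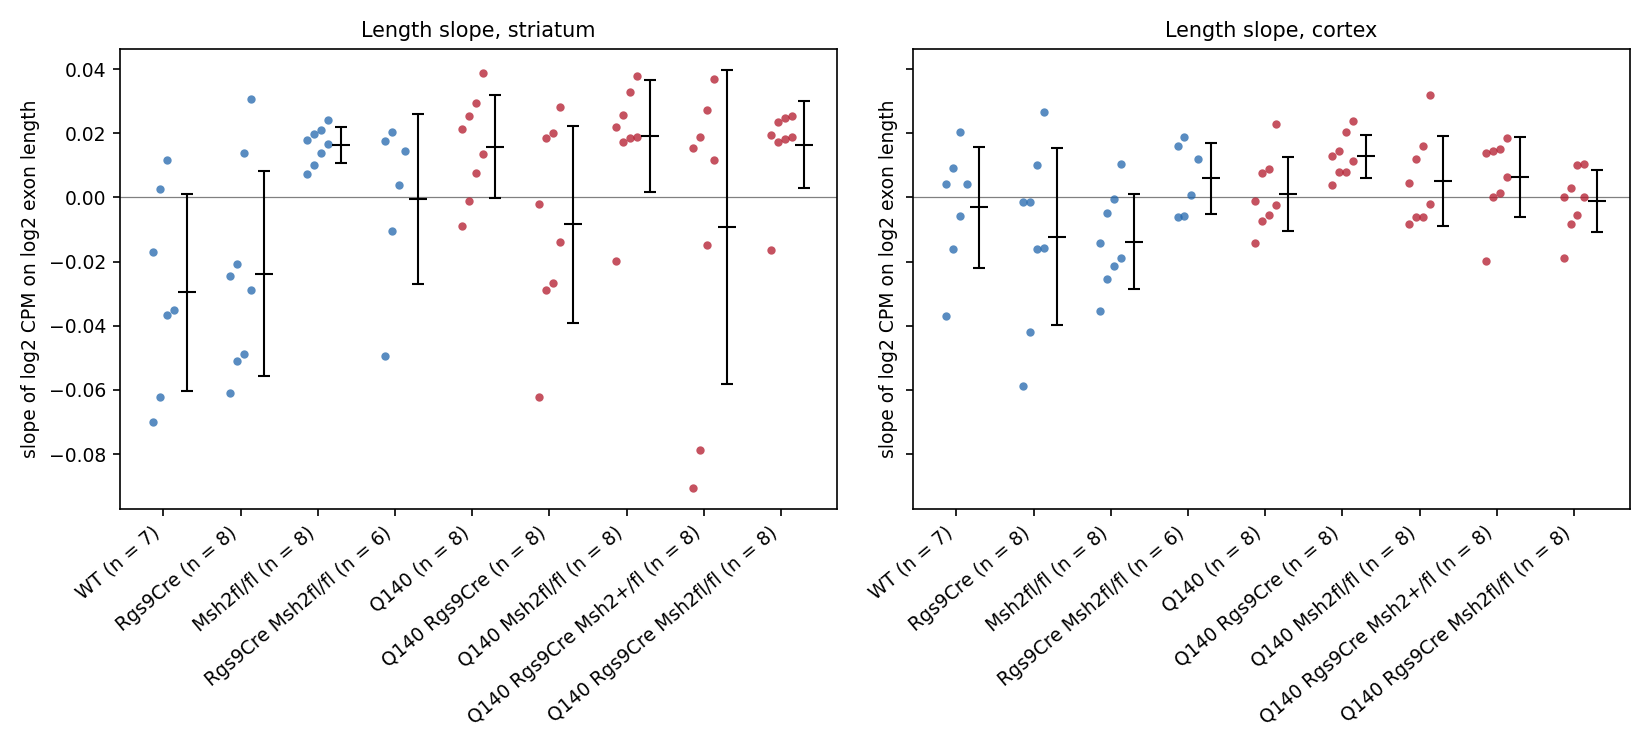
Length slope of each library (vertical axis, change of log2 CPM per unit of log2 exon length, no further unit) in each genotype (horizontal axis), with striatum and cortex in separate panels. Points are libraries and black bars are group means ± SD; the lowest striatal points belong to WT, Rgs9Cre, Q140 Rgs9Cre, Q140 Rgs9Cre Msh2+/fl and Rgs9Cre Msh2fl/fl.

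The first comparison asked what 1 Q140 allele does to striatal RNA on the plain background. In Q140 striatum genes of projection neurons fell. Of 49 measured projection neuron markers, 44 were lower and 2 higher in Q140 than in WT, with a median log2 change of −0.67. Penk (ENSMUSG00000045573), the precursor of enkephalin, went from 1830 ± 136 CPM (SD, n = 7) in WT to 608 ± 37.9 CPM (n = 8) in Q140, a 3.01-fold lower level. Of 19095 genes tested, 3996 were higher and 3870 lower in Q140, and 197 and 390 of these changed at least by a factor of 2.

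The largest falls were led by Gpx6 and Abhd11os. Gpx6 (ENSMUSG00000004341, chromosome 13, 21312125 to 21319624), a glutathione peroxidase, was 29.9-fold lower, at 0.540 ± 0.112 CPM (n = 8) against 16.2 ± 3.62 CPM (n = 7) in WT (log2 change −4.90 ± 0.19 SE, edgeR adjusted p = 1.9e-32). Ryr1 (ENSMUSG00000030592), the ryanodine receptor calcium channel, was 7.26-fold lower, at 24.0 ± 3.44 against 174.7 ± 31.9 CPM (log2 change −2.86 ± 0.10 SE, adjusted p = 9.0e-35). Ddit4l, an inhibitor of mTOR signalling, was 6.10-fold lower (log2 change −2.61 ± 0.07 SE, adjusted p = 1.1e-40). The noncoding RNA Abhd11os was 10.3-fold, the membrane transporter Slc4a11 7.42-fold, Sec14l3 6.74-fold and Vwa7 6.73-fold lower. Gm9754 at 5.82-fold, the unconventional myosin Myo5c at 5.01-fold and the immediate early transcription factor Egr2 at 4.41-fold lower completed the set. Rgs9 was 1.93-fold lower (log2 change −0.95 ± 0.06 SE, adjusted p = 2.5e-20), and Msh2 was 1.14-fold higher (log2 change 0.19 ± 0.04 SE, adjusted p = 2.7e-05).

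The largest rises were led by Nrn1 and Sfmbt2. Nrn1 (ENSMUSG00000039114, chromosome 13, 36725361 to 36735131), which encodes the neurite growth protein neuritin, was 13.9-fold higher, at 16.9 ± 4.50 CPM (n = 8) in Q140 against 1.22 ± 0.297 CPM (n = 7) in WT (log2 change 3.79 ± 0.31 SE, adjusted p = 1.3e-16). Sfmbt2, a Polycomb group protein, was 5.94-fold higher (log2 change 2.57 ± 0.10 SE, adjusted p = 1.4e-33). Tmc3 was 4.95-fold, the desmosomal protein gene Dsp 4.33-fold and the protocadherin Pcdh20 4.16-fold higher. AW551984 at 3.83-fold, Ipcef1 at 3.23-fold, Fam196b at 3.14-fold, Pcdhb2 at 3.10-fold and Gm43305 at 3.01-fold followed.

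Among the 29 gene lists, 9 passed the camera test with its preset correlation. Apart from the Hox genes, only the fall of the projection neuron markers also held with an estimated correlation (46 of 49 called over the list alone, 44 of them lower; camera adjusted p = 4.6e-39, and adjusted p = 0.0017 with an estimated correlation). Besides Penk, Arpp21, a phosphoprotein enriched in projection neurons, was 2.09-fold and Ptprv 3.14-fold lower. Of 39 Hox genes, which pattern the body axis, 4 passed the low-count filter, and these 4 were higher over all genes and adjusted over the list alone. Hoxc4, Hoxc5 and Hoxc6 have 1, 0 and 0 counts in WT, so they could be tested only because other groups express them. The filter thus fixed the direction of the list before its test (camera adjusted p = 0.00028, and adjusted p = 0.0404 with an estimated correlation), which shows nothing beyond these genes. Their median log2 change was 7.80 as fitted and 6.07 with genes without counts in WT set at their bound. Hoxa7 was 3.80-fold higher. Hoxc4 had 863 counts over the Q140 group and 1 over the WT group, a depth-adjusted ratio of 735.8 with a 95% counting interval of 131.7 to 29090. Hoxc5 had 453 counts and Hoxc6 124 counts in Q140 and 0 in all WT libraries, which makes them at least 128.7-fold and at least 35.2-fold higher against a floor of 3 counts over the group. These intervals and floors cover counting error only.

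The other 7 lists passed with the preset correlation only. Of 20 immediate early genes, 13 were lower and 2 higher (15 and 2 adjusted over the list alone; median log2 change −0.65), including Per1 at 1.76-fold, Dusp1 at 1.79-fold and Jun at 1.36-fold lower (adjusted p = 0.633 with an estimated correlation). Of 57 clustered protocadherins, cell adhesion genes with near-identical copies between which the counting could split reads, 31 were higher and 2 lower (34 and 2 over the list alone). Pcdhb3 was 2.15-fold and Pcdhb9 1.71-fold higher, and the list had an adjusted p = 0.633 with an estimated correlation. Of 38 developmental transcription factors, 13 were higher and 2 lower (14 and 3 over the list alone; adjusted p = 0.136 with an estimated correlation), where 41.19% of all genes tested were called. Wt1, a zinc finger factor of kidney and gonad development, was 44.5-fold, Onecut1 149.9-fold, the sensory neuron factor Pou4f1 13.3-fold and Pax6 2.10-fold higher. Members near 0 CPM in WT, such as Onecut1, entered this list test in the same way as the Hox genes. Shox2, a homeobox factor of limb development chosen after its values were seen, had a log2 change of 7.18 ± 0.44 SE. Synaptic vesicle and release genes were higher in 13 and lower in 2 of 26 (14 and 3 over the list alone), with Syp at 1.61-fold and Sv2a and Syn1 at 1.28-fold higher (adjusted p = 0.633 with an estimated correlation). Glutamate receptor and postsynaptic density genes were lower in 14 and higher in 8 of 29 (the same counts over the list alone), with the kainate receptor Grik2 1.81-fold, Shank3 1.57-fold, Camk2b 1.33-fold and Dlg4 1.29-fold lower (adjusted p = 0.781 with an estimated correlation).

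Oxidative phosphorylation genes were lower in 28 and higher in 4 of 90 (27 and 4 adjusted over the list alone; median log2 change −0.10), with Cox4i2 1.70-fold and Ndufs3 1.29-fold lower and Atp5b 1.11-fold higher. Cytosolic ribosomal protein genes, many with processed copies in the genome, were lower in 18 and higher in 2 of 85 (15 and 2 over the list alone; median log2 change −0.11). Rpl31 was 1.30-fold lower and Rps15a 1.11-fold higher. Both lists had a camera adjusted p = 0.0406 and an adjusted p = 0.837 with an estimated correlation. The length slope averaged 0.02 in Q140 and −0.03 in WT striatum.

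Markers of other cell types and the remaining pathways did not pass as lists. Microglia markers were lower in 7 of 18 (6 over the list alone; camera adjusted p = 0.0672), endothelial and mural markers in 7 of 17 (0.0526) and mature oligodendrocyte markers in 7 of 21 with 3 higher (0.117). Oligodendrocyte precursor markers were higher in 4 and lower in 1 of 14 (0.113). Astrocyte markers were lower in 4 and higher in 1 of 17 (0.655), where the median log2 change of 0.02 and the mean of −0.03 differed in sign. Reactive astrocyte genes were lower in 5 and higher in 2 of 17 (0.255), disease-associated microglia genes lower in 2 of 16 (1 over the list alone; 0.633) and striatal interneuron markers lower in 3 of 18 (0.287). Mismatch repair and CAG repeat instability genes were higher in 10 and lower in 4 of 28 (0.0671), and genes of the p53 and DNA damage response lower in 9 and higher in 3 of 28 (0.113).

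Stress, immune and neighbouring-region lists did not pass either. Interferon response genes were lower in 8 and higher in 1 of 30 (8 and 0 adjusted over the list alone; camera adjusted p = 0.118), heat shock and chaperone genes higher in 6 and lower in 2 of 22 (0.236) and cholesterol biosynthesis genes higher in 5 and lower in 3 of 25 (0.465). Mitochondrially encoded genes were lower in 5 of 23 (0.113). Potassium channels were lower in 16 and higher in 12 of 80 (0.543), with a median log2 change of 0.06 where the test pointed down. Cortical excitatory neuron markers, which a neighbouring region could bring into a dissection, were higher in 7 and lower in 2 of 20 (0.287). Thalamic and hypothalamic markers were lower in 2 of 10 (1 over the list alone; 0.795), with a median of −0.01 and a mean of 0.07. Choroid plexus and ependymal markers were higher in 3 of 17 (0.748), with a median of −0.09 where the test pointed up. Fibroblast and meningeal markers were lower in 2 and higher in 1 of 12 (2 and 0 over the list alone; 0.945), and no blood cell gene of 6 was called (0.748). Where no second count is given, the count adjusted over the list alone was the same.

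The same comparison was repeated on 3 further backgrounds to see what the knock-in allele did with Cre, with the floxed alleles and with both. The same leading genes changed in each. Gpx6 was 28.9-fold lower in Q140 Rgs9Cre than in Rgs9Cre, 18.9-fold lower in Q140 Msh2fl/fl than in Msh2fl/fl and 10.6-fold lower in Q140 Rgs9Cre Msh2fl/fl than in Rgs9Cre Msh2fl/fl. Nrn1 was 8.74-fold, 9.89-fold and 6.55-fold higher and Sfmbt2 5.51-fold, 5.30-fold and 5.44-fold higher in the same order. Ryr1 was 5.67-fold, 6.35-fold and 4.70-fold lower, Ddit4l 6.69-fold, 6.70-fold and 5.90-fold lower and Rgs9 1.86-fold, 1.94-fold and 1.74-fold lower.

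Projection neuron markers fell on each of these backgrounds. Among the 49 markers, 44 were lower with Rgs9Cre (46 adjusted over the list alone), 44 with Msh2fl/fl (46 over the list alone) and 43 with Rgs9Cre Msh2fl/fl (45 over the list alone), and 1 was higher in each (1, 1 and 2 over the list alone). The adjusted p with an estimated correlation was 0.000494, 0.000236 and 0.00053. The 4 Hox genes that passed the filter were again higher in each, over all genes and adjusted over the list alone, with median log2 changes of 7.06, 6.81 and 7.11 as fitted and 6.21, 5.94 and 6.08 with genes without counts at their bound (adjusted p = 0.01195, 0.0379 and 0.0082 with an estimated correlation). The filter fixed the direction of this list test too, since the controls hold Hoxc4, Hoxc5 and Hoxc6 at or near 0 CPM. Glutamate receptor and postsynaptic density genes were lower in 20, 20 and 15 of 29 (20, 20 and 16 over the list alone), a call that ended with an estimated correlation (adjusted p = 0.483, 0.2075 and 0.565).

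In all, 3213 genes were higher and 3150 lower with Rgs9Cre, 3584 and 3273 with Msh2fl/fl, and 2504 and 2753 with Rgs9Cre Msh2fl/fl. Genes called on the plain background were compared with each of these, which share no library with it. Called higher in both were 2523 genes with Rgs9Cre (672.4 for independent lists), 2257 with Msh2fl/fl (750) and 2142 with Rgs9Cre Msh2fl/fl (524). Called lower in both were 2546 (638.4), 2272 (663.3) and 2372 (558). Only 3, 5 and 1 genes were called in opposite directions. Of the 7866 genes called on the plain background, 97.2%, 91.8% and 97.8% had the same sign on the other backgrounds.

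**Figure D2:**
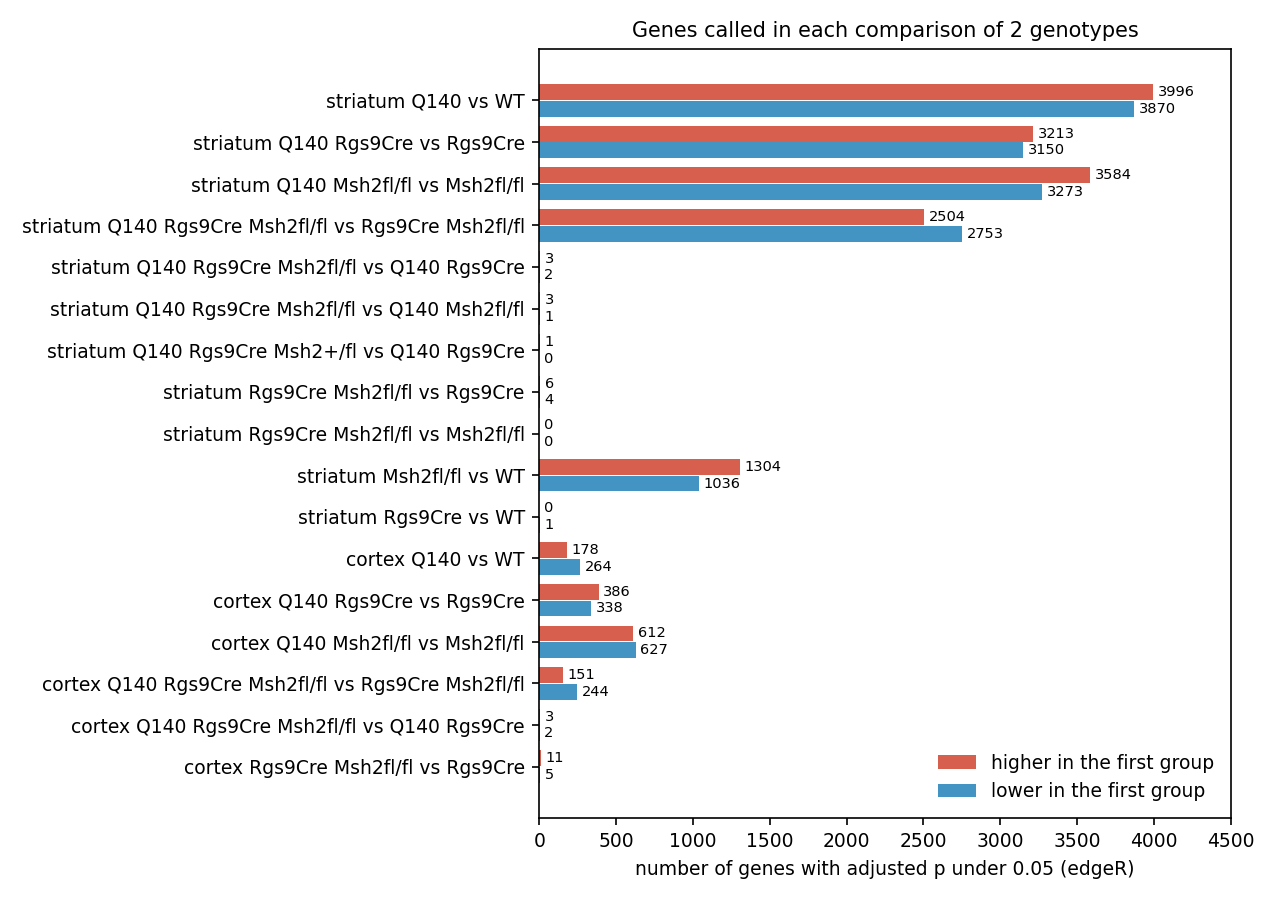
Number of genes higher and lower (horizontal axis, genes at an edgeR adjusted p under 0.05) in each comparison between genotypes (vertical axis). Bars are counts of genes, and the 4 striatal comparisons of Q140 carriers with their controls run from 5257 to 7866 genes in all while striatal Q140 Rgs9Cre Msh2fl/fl against Q140 Rgs9Cre has 5.

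Whether the Q140 effect differed between the tissues was tested in the 15 WT and Q140 mice with both regions. The effect was higher in striatum for Wt1 and Nrn1 and lower there for Ryr1 and Rgs9, and gene lists were not tested for this difference. The Q140 effect on Wt1 was larger in striatum by 6.32 ± 0.32 (SE) on the log2 scale, on Shox2 by 6.05 ± 0.99, on Nrn1 by 3.95 ± 0.15, on Sfmbt2 by 2.56 ± 0.11, on Dsp by 2.53 and on Pcdh20 by 1.98. Neurod2, a transcription factor of cortical excitatory neurons, differed by 2.26 ± 0.30. The effect was lower in striatum for Sec14l3 (−2.79), Vwa7 (−2.70), Ryr1 (−2.67 ± 0.11), Abhd11os (−2.49), Ddit4l (−2.10 ± 0.11) and Rgs9 (−0.93 ± 0.09; edgeR adjusted p = 1.1e-07). For Msh2 the difference was 0.27 ± 0.05 (adjusted p = 0.00066) and for Htt 0.18 ± 0.09 (adjusted p = 0.173). The difference passed for 5079 of 18841 genes, 2597 with a higher and 2482 with a lower effect in striatum.

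In cortex the Q140 allele changed fewer genes, and an oligodendrocyte gene and astrocyte genes were among them. Enpp6 (ENSMUSG00000038173, chromosome 8, 46986887 to 47096762), a choline phosphodiesterase of newly forming oligodendrocytes, was 2.54-fold higher in Q140 than in WT, at 5.71 ± 0.673 CPM (SD, n = 8) against 2.24 ± 0.387 CPM (n = 7; log2 change 1.35 ± 0.12 SE, edgeR adjusted p = 2.8e-13). Plk5, a polo-like kinase of brain, was 2.01-fold lower, at 12.2 ± 2.16 against 24.4 ± 3.05 CPM (log2 change −1.01 ± 0.11 SE, adjusted p = 8.7e-10). Of 17 astrocyte markers, 7 were lower and none higher (11 and 0 adjusted over the list alone; camera adjusted p = 4.9e-12, and adjusted p = 0.0305 with an estimated correlation). Glutamine synthetase, Glul, went from 1749 ± 58.8 CPM (n = 7) in WT to 1446 ± 48.0 CPM (n = 8), 1.21-fold lower, and the bicarbonate transporter Slc4a4 at 1.31-fold, the glutamate transporter Slc1a2 at 1.21-fold and Aldoc at 1.22-fold were lower too.

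Further cortical rises were Abhd1 at 2.36-fold, Chdh at 1.77-fold, Anln at 1.76-fold, Nfe2l3 at 1.69-fold, Col12a1 and C230034O21Rik at 1.57-fold, Abca8a at 1.53-fold, and Rprm and Gm42864 at 1.52-fold. Further falls were Cyr61 at 2.12-fold, the myosin gene Myh7 at 1.94-fold, Gbp4 at 1.80-fold, Sytl1 at 1.76-fold, Proser2 at 1.75-fold, Lrrc32 at 1.72-fold, Gm765 at 1.71-fold, Cabp7 at 1.68-fold and Gpr153 at 1.64-fold. Gbp4 did not pass with only these groups in the fit (log2 change −0.85, adjusted p = 0.133), with the plate column as a covariate (−0.77, adjusted p = 0.0565) or with limma voom (−0.63, adjusted p = 0.0613), and Cyr61 did not with the mouse number as a covariate (−0.97, adjusted p = 0.0706). In all, 178 genes were higher and 264 lower of 18840 tested, and limma voom called 854 in total. Htt had a log2 change of −0.14 ± 0.05 SE (adjusted p = 0.0948). It passed at −0.14 with only these groups in the fit (adjusted p = 0.0321), with limma voom (adjusted p = 0.0072) and without the libraries of extreme slope (adjusted p = 0.0099), and at −0.15 with the slope as a covariate (adjusted p = 0.0223). Msh2 had a log2 change of −0.09 (adjusted p = 0.243) and Rgs9 of −0.03 (adjusted p = 0.948).

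Other cortical lists passed with the preset correlation only. Of 80 potassium channels, 5 were lower (9 lower and 1 higher adjusted over the list alone), among them the fast-firing channels Kcnc3 (log2 change −0.32) and Kcnc1 at 1.13-fold and also Kcnk6 at 1.21-fold and Kcnip2 at 1.13-fold lower (adjusted p = 0.206 with an estimated correlation). No immediate early gene of 20 was called over all genes in this edgeR fit, against 5 lower over the list alone (adjusted p = 0.576 with an estimated correlation). Egr2 had a log2 change of −1.13, Btg2 of −0.81, Dusp1 of −0.74 and Npas4 of −0.58. With only these groups in the fit Btg2 (adjusted p = 0.0227), Egr2 (adjusted p = 0.0323) and Dusp1 (adjusted p = 0.0145) passed over all genes. With limma voom Btg2 (adjusted p = 0.0211) and Egr2 (adjusted p = 0.0351) did, and so did both with Xist as a covariate, and Btg2 with the sex label or the replicate number. Insig1 of the cholesterol list was 1.35-fold lower (1 of 25 lower, 2 over the list alone; adjusted p = 0.576 with an estimated correlation), and Ddit4l at 1.44-fold and Gadd45b at 1.37-fold lower were the 2 called of 28 p53 and DNA damage genes (4 over the list alone; adjusted p = 0.206 with an estimated correlation). With the plate column as a covariate Gadd45b (log2 change −0.45, adjusted p = 0.0596) and Kcnip2 (−0.15, adjusted p = 0.0875) did not pass. Ribosomal protein genes and fibroblast and meningeal markers had no member called, over all genes or over the list alone (adjusted p = 0.764 and 0.730 with an estimated correlation).

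On the other backgrounds Enpp6 was again higher and Plk5 lower in cortex of Q140 carriers. Enpp6 rose 2.71-fold with Rgs9Cre, 2.77-fold with Msh2fl/fl and 2.54-fold with Rgs9Cre Msh2fl/fl, and Plk5 fell 2.29-fold, 1.90-fold and 2.08-fold. Glul was 1.19-fold, 1.23-fold and 1.20-fold lower. With Rgs9Cre, 386 genes were higher and 338 lower, with Msh2fl/fl 612 and 627, and with Rgs9Cre Msh2fl/fl 151 and 244. On the last background potassium channels fell as a list (5 of 80 lower, 12 lower and 1 higher adjusted over the list alone; adjusted p = 0.0297 with an estimated correlation), with Kcnc3 lower by a log2 change of −0.32 and Kcnc1 1.13-fold lower, and Htt had a log2 change of −0.19 ± 0.05 SE (adjusted p = 0.0185). Genes called in Q140 against WT were also called higher in 88, 88 and 66 cases on these backgrounds (3.65, 5.78 and 1.43 for independent lists) and lower in 121, 124 and 118 cases (4.74, 8.79 and 3.42), with 0 in opposite directions. The count with Rgs9Cre fell from 724 to 332 without the libraries of extreme length slope and to 236 with only its own groups in the fit, and that with Msh2fl/fl from 1239 to 674 with the length slope as a covariate and to 759 with only its own groups.

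Floxed and unfloxed Msh2 were then compared in the striatum of Q140 carriers with Cre. Between Q140 Rgs9Cre Msh2fl/fl and Q140 Rgs9Cre, 5 genes of 19095 differed, and 4 of them lie on chromosome 17 within 20 Mb of Msh2. Gm6969 (ENSMUSG00000066553, chromosome 12, 24638669 to 24639010) was 2.34-fold higher, at 39.8 ± 2.05 against 16.9 ± 6.50 CPM (SD, n = 8 each; log2 change 1.23 ± 0.13 SE, edgeR adjusted p = 4.9e-10). Cox7a2l (ENSMUSG00000024248, chromosome 17, 83501918 to 83517330), an assembly factor of respiratory chain supercomplexes, was 1.45-fold lower, at 53.8 ± 2.02 against 78.2 ± 7.55 CPM (log2 change −0.54 ± 0.07 SE, adjusted p = 2.3e-06). The sequence of Gm6969 is 97.95% identical to Cox7a2l over 342 bases, so the counting could split reads between them and the change of each is uncertain. Gpatch11 was 1.27-fold higher (adjusted p = 0.00018) and Cebpzos, named as the opposite-strand gene of Cebpz, 1.47-fold lower (adjusted p = 0.0108). Gpatch11 did not pass with only these groups in the fit (log2 change 0.34, adjusted p = 0.127), nor Cebpzos with the replicate number as a block (−0.52, adjusted p = 0.0597). The strand setting of the counting is not given in the sources used here, so reads of a gene and its opposite-strand partner, Abhd11os included, cannot be told apart. The last gene, C430042M11Rik, was higher and was chosen after its values were seen, and its call ended in both of these settings and with the plate column.

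No projection neuron marker was called over all genes in that edgeR comparison, while Penk passed with the length slope as a covariate (log2 change 0.20, adjusted p = 0.0372). Rgs9 had a log2 change of 0.20 ± 0.06 SE (adjusted p = 0.402) and Msh2 of 0.11 (adjusted p = 0.441). Over all genes 0 of 49 markers were called, and 13 were higher adjusted over the list alone. Fitted changes were above 0 for 44 of 49, and camera passed with its preset correlation but not otherwise (adjusted p = 0.400 with an estimated correlation). Glutamate receptor and postsynaptic density genes were higher in 10 of 29 over the list alone (adjusted p = 0.400 with an estimated correlation). Mitochondrially encoded genes were lower in 4 of 23 over the list alone (adjusted p = 0.562 with an estimated correlation), beside a mean mitochondrial share of 5.67% against 6.35% and a mean length slope of 0.02 against −0.01. In simulated libraries of this comparison, 40 of 50 genes changed 1.25-fold, 49 of 50 changed 1.5-fold and all 50 changed 2-fold were recovered. The simulated libraries lacked the spread particular to single genes and the length slope differences of the real ones. These shares may therefore overstate what the real libraries allow. The total was 3 with only these groups in the fit, 8 with the length slope as a covariate and 15 with limma voom.

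Against Q140 Msh2fl/fl, which carries the floxed alleles without Cre, projection neuron genes were higher in Q140 Rgs9Cre Msh2fl/fl. Ryr1 was 1.47-fold higher, at 35.1 ± 5.47 against 23.9 ± 2.23 CPM (SD, n = 8 each; log2 change 0.55 ± 0.10 SE, edgeR adjusted p = 0.0043). The unconventional myosin Myo3b was 1.56-fold higher (adjusted p = 0.016) and Gm11696 1.45-fold lower (adjusted p = 0.0091), and Gm10706, chosen after its values were seen, completed the 4 genes called. Myo3b did not pass with the plate column as a covariate (log2 change 0.61, adjusted p = 0.0675) or with the replicate number as a block (0.59, adjusted p = 0.0586), and neither did Gm10706. Gm11696 did not with only these groups in the fit (−0.54, adjusted p = 0.0877) or with the block (−0.53, adjusted p = 0.0524). Of 49 projection neuron markers 1 was higher over all genes in edgeR and 32 adjusted over the list alone, and fitted changes were above 0 for 47. Further markers passed over all genes with DESeq2 and with limma voom, namely Penk (adjusted p = 0.0393 and 0.0015), Ptpn5 (0.0207 and 0.0200) and Foxp1 (0.0443 and 0.0200), and Foxp1 also with only these groups in the fit (0.0455). The median log2 change was 0.17, and the list held with an estimated correlation (camera adjusted p = 2.4e-35, and adjusted p = 0.0037 with an estimated correlation).

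The mean log2 CPM of these 49 markers stood at 8.575 in WT and 7.852 in Q140 striatum. It was 7.965 ± 0.064 (SD, n = 8) in Q140 Rgs9Cre Msh2fl/fl, 7.798 ± 0.109 (n = 8) in Q140 Msh2fl/fl and 7.841 ± 0.079 (n = 8) in Q140 Rgs9Cre. The rise over Q140 Msh2fl/fl was 0.166 (exact permutation p = 0.0025, two-sided), and that over Q140 Rgs9Cre was 0.124 (exact permutation p = 0.0042, two-sided). As a list the markers did not pass against Q140 Rgs9Cre with an estimated correlation (adjusted p = 0.400). The length slope averaged 0.0164 in Q140 Rgs9Cre Msh2fl/fl and −0.00839 in Q140 Rgs9Cre, and the mitochondrial share 5.67% and 6.35%. The difference from Q140 Rgs9Cre was 0.113 with the length slope held (exact permutation p = 0.0044) and 0.115 with the mouse number held (exact permutation p = 0.0016). Q140 Rgs9Cre differed from Q140 by −0.0117 (exact permutation p = 0.760). These tests per mouse were chosen after the list result was seen.

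**Figure D3:**
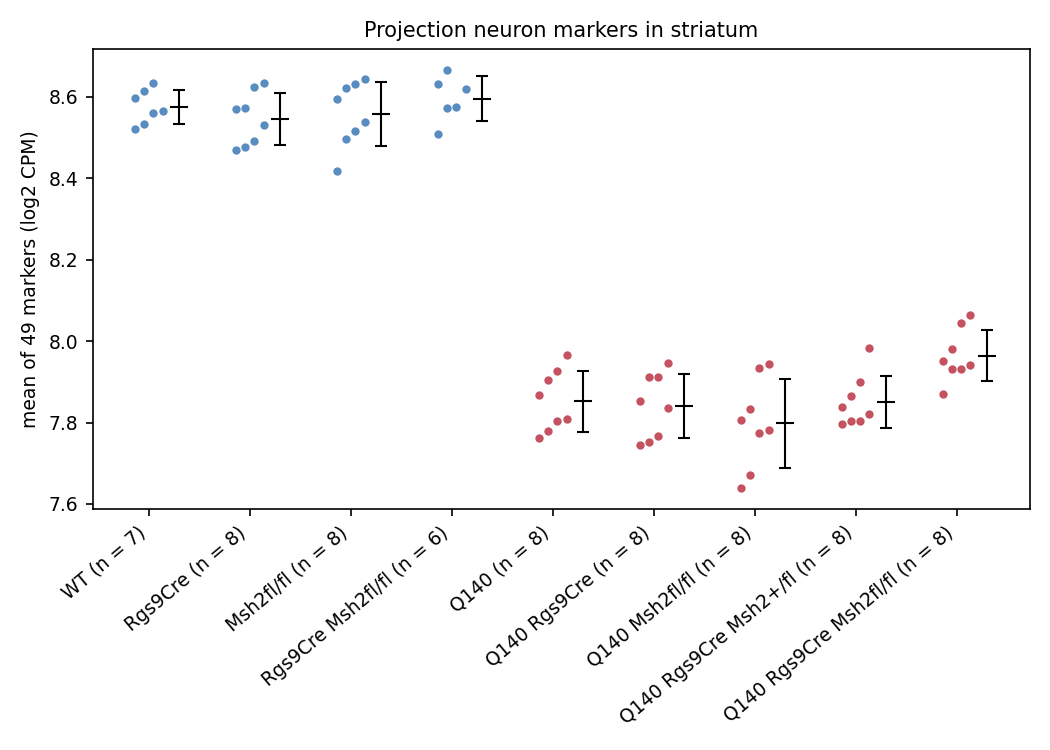
Mean log2 CPM of the 49 striatal projection neuron markers (vertical axis) in striatal libraries of each genotype (horizontal axis). Points are libraries and black bars are group means ± SD; Q140 carriers lie below genotypes without Q140, and Q140 Rgs9Cre Msh2fl/fl averages 7.965.

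Other lists of this comparison passed with the preset correlation only. Glutamate receptor and postsynaptic density genes were higher in 4 of 29 over the list alone (adjusted p = 0.385 with an estimated correlation), and choroid plexus and ependymal markers lower in 7 of 17 over the list alone (adjusted p = 0.522 with an estimated correlation). DESeq2 called 27 genes in total, 88.9% of them higher against 75% in edgeR, limma voom called 70, and edgeR called 21 without the libraries of extreme length slope and 39 with the slope as a covariate. With only these groups in the fit 10 were called, with the plate column as a covariate 2 and with the mouse number 8.

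Q140 Rgs9Cre Msh2+/fl, with 1 floxed Msh2 allele, was compared with Q140 Rgs9Cre. Gm6969 was the only gene called by edgeR, 1.76-fold higher at 29.9 against 16.9 CPM (log2 change 0.81 ± 0.13 SE, adjusted p = 0.00032, n = 8 each). Microglia markers had a median log2 change of −0.10 and heat shock and chaperone genes of −0.07, with 0 members called over all genes or over the list alone (adjusted p = 0.269 and 0.382 with an estimated correlation). Unadjusted p lay under 0.05 for 794 genes. With only these groups in the fit 0 genes were called, at a log2 change of 0.81 for Gm6969, and limma voom or leaving out the libraries of extreme length slope gave 2.

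Whether the Q140 effect itself differed on the background of Cre with floxed Msh2 was tested as an interaction. Against the background with Rgs9Cre alone, the fall of Gpx6 was smaller with Rgs9Cre Msh2fl/fl by 1.44 ± 0.28 (SE) on the log2 scale (edgeR adjusted p = 0.0387). Satb2, a transcription factor of cortical projection neurons chosen after its values were seen, had an interaction of −2.45. These were the 2 genes called, against 382 at an unadjusted p under 0.05. DESeq2 called 3 and limma voom 0. Both calls ended with only these groups in the fit, with the plate column as a covariate, with the replicate number as a block and with limma voom, at interactions of 1.44, 1.39, 1.37 and 1.54 for Gpx6 and −2.45, −2.45, −2.36 and −1.79 for Satb2. Against the background with Msh2fl/fl alone, edgeR, DESeq2 and limma voom each called 0 genes, and 934 had an unadjusted p under 0.05. Projection neuron markers had a median interaction of 0.07 against Rgs9Cre and 0.11 against Msh2fl/fl, with 0 members called over all genes or over the list alone (adjusted p = 0.815 and 0.4175 with an estimated correlation).

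The Q140 response was summarised by the signature score of the 3996 genes higher and 3870 lower in Q140 than WT striatum. It was read in the 7 genotypes that did not choose the genes. The Q140 effect on the score was 0.631 with Rgs9Cre Msh2fl/fl and 0.668 with Rgs9Cre. Thus 94.4% remained (95% bootstrap interval 79.5% to 115.1%, permutation p = 0.596, two-sided). The score was 0.895 ± 0.047 (SD, n = 8) in Q140 Rgs9Cre Msh2fl/fl and 0.871 ± 0.077 (n = 8) in Q140 Rgs9Cre, which did not differ (exact permutation p = 0.463, two-sided). It was lower by 0.075 than in Q140 Msh2fl/fl, whose mean was 0.970 (exact permutation p = 0.0334). Q140 Rgs9Cre Msh2+/fl and Q140 Rgs9Cre differed by −0.01 (exact permutation p = 0.868), and Rgs9Cre Msh2fl/fl and Rgs9Cre by 0.06 (exact permutation p = 0.326). Without Q140 the score averaged 0.119 in WT, 0.203 in Rgs9Cre and 0.354 in Msh2fl/fl, so more than Q140 may move it. The lowest carrier stood at 0.508 and the highest mouse without Q140 at 0.453.

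The difference between Q140 Rgs9Cre Msh2fl/fl and Q140 Rgs9Cre turned sign with the choice of genes and with the length slope. It was −0.0943 with genes taken from Q140 Msh2fl/fl against Msh2fl/fl (exact permutation p = 0.0051), −0.152 with the 50 genes of largest change in each direction (exact permutation p = 0.0298) and −0.0635 with the length slope as a covariate (permutation p = 0.0126). It was −0.0228 without the libraries of extreme slope and −0.0220 with genes of an absolute log2 change of at least 0.5, where it did not pass. The settings with 50 genes and with the slope were chosen after seeing the data. The permutation test of the percentage remaining passed 0.05 in none of these settings.

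In cortex the score of 178 higher and 264 lower genes gave 97.5% remaining, with a 95% bootstrap interval of 81.7% to 119.1% (permutation p = 0.807). Q140 Rgs9Cre Msh2fl/fl differed from Q140 Rgs9Cre by 0.0059 (exact permutation p = 0.905) and from Q140 Msh2fl/fl by 0.044 (exact permutation p = 0.365). Q140 Rgs9Cre Msh2+/fl differed from Q140 Rgs9Cre by −0.01 (exact permutation p = 0.822), and Rgs9Cre Msh2fl/fl from Rgs9Cre by 0.02 (exact permutation p = 0.599). Cortical scores of carriers began at −0.561 and those of mice without Q140 ended at −0.775.

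**Figure D4:**
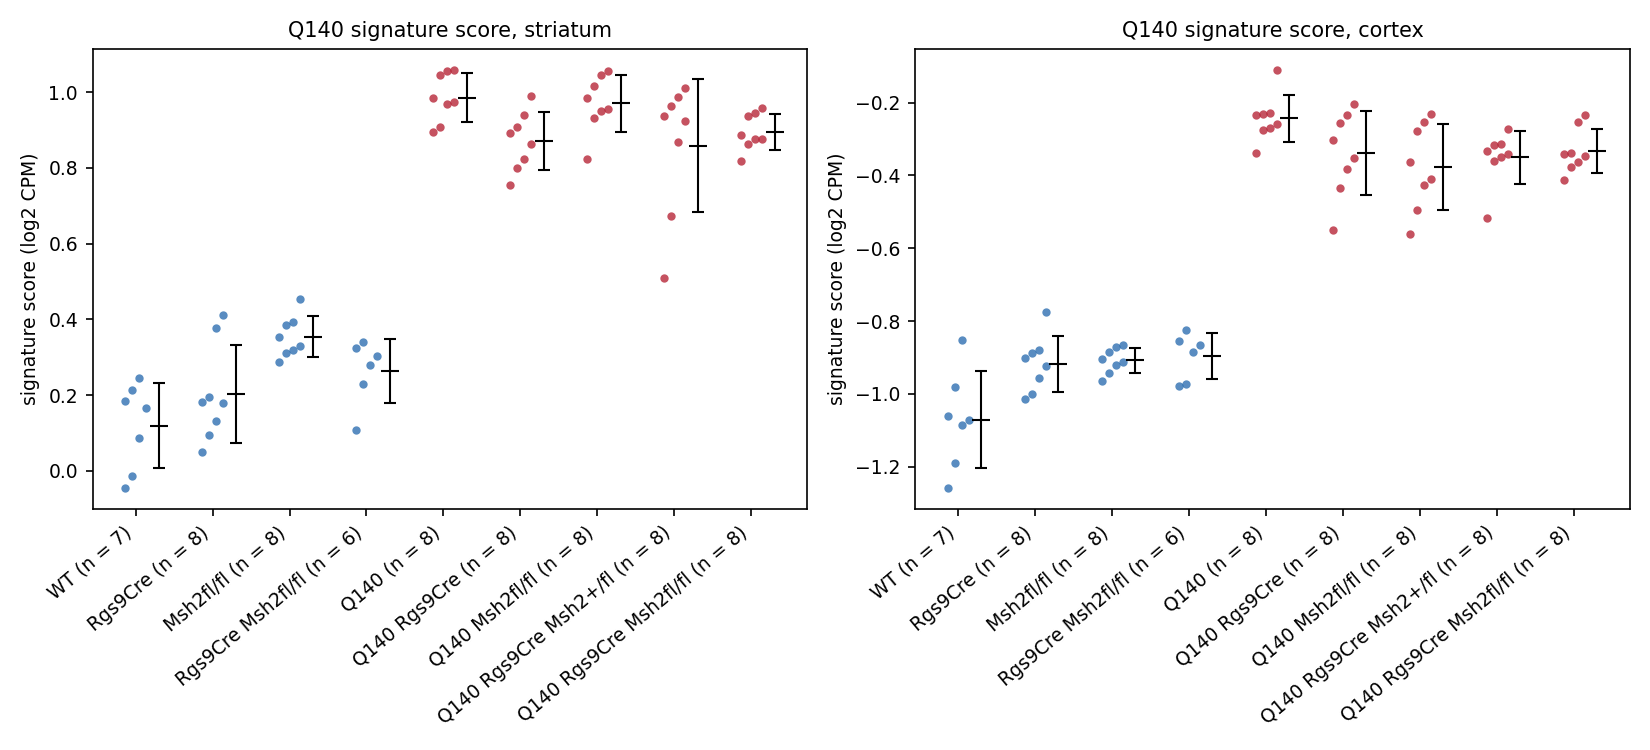
Q140 signature score (vertical axis, difference of mean log2 CPM) in libraries of each genotype (horizontal axis), with striatum and cortex in separate panels; WT and Q140 chose the genes. Points are libraries and black bars are group means ± SD, and among the other 7 genotypes each Q140 carrier lies above each mouse without Q140 in both tissues.

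The cortex of the same mice was compared because Rgs9 is expressed there at a low level. Between Q140 Rgs9Cre Msh2fl/fl and Q140 Rgs9Cre cortex, 3 genes were higher and 2 lower. Gm6969 was 2.66-fold higher, at 41.9 against 15.7 CPM (n = 8 each, edgeR adjusted p = 1.2e-10), and Cox7a2l 1.5-fold lower (adjusted p = 3.1e-11). Gpatch11 was 1.35-fold higher (adjusted p = 0.00064), Msh2 1.12-fold higher (adjusted p = 0.0436) and Ttc7 1.44-fold lower (adjusted p = 1.6e-06). Interferon response genes had a median log2 change of −0.13 with 0 of 30 called over all genes or over the list alone (adjusted p = 0.907 with an estimated correlation). With only these groups in the fit 3 genes were called. Gpatch11 (log2 change 0.44, adjusted p = 0.0693) and Msh2 (0.17, adjusted p = 0.913) were not among them, and Msh2 did not pass without the low-count filter (0.17, adjusted p = 0.102) or with the mouse number as a covariate (0.16, adjusted p = 0.0686).

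In mice without Q140, genes of the same neighbourhood differed between Cre carriers with floxed and with unfloxed Msh2. Between Rgs9Cre Msh2fl/fl and Rgs9Cre striatum, Gm6969 was 2.98-fold higher, at 42.7 ± 4.62 (SD, n = 6) against 14.3 ± 1.22 CPM (n = 8; log2 change 1.57 ± 0.14 SE, edgeR adjusted p = 2.8e-13), and Cox7a2l 1.44-fold lower (adjusted p = 3.1e-05). Gpatch11 was 1.39-fold higher (adjusted p = 2.1e-07), and Ndufaf7, of respiratory complex I assembly, 1.20-fold lower (adjusted p = 0.0033). Ntng1 was 1.41-fold higher and S100a10 1.5-fold and Mcfd2 1.12-fold lower, each at an adjusted p = 0.043, and these 3 calls ended in several of the other settings. Satb2, Serpinb8 and C430042M11Rik, of low expression and chosen after their values were seen, were higher and made up 6 higher and 4 lower genes, and the calls of Satb2 and Serpinb8 ended in some settings as well. Mitochondrially encoded genes were lower in 6 of 23 over the list alone and in none over all genes (adjusted p = 0.546 with an estimated correlation), beside a mean mitochondrial share of 5.68% against 6.44%. DESeq2 called 16 genes, and 5 were called with only these groups in the fit and 6 with the length slope or with the mouse number as a covariate.

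In cortex the same comparison gave 11 higher and 5 lower genes. Gm6969 was 3.19-fold, Gpatch11 1.56-fold, Heatr5b 1.26-fold and Lrpprc, an RNA-binding protein of mitochondria, 1.13-fold higher. Msh2 was 1.20-fold higher (log2 change 0.26 ± 0.04 SE, adjusted p = 1.2e-05), and Cox7a2l was 1.67-fold and Ttc7 1.35-fold lower. Without Cre, cortical Msh2 stood at 34.77 ± 1.84 CPM (SD, n = 8) in Msh2fl/fl and 31.05 ± 0.971 CPM (n = 7) in WT. With Q140 it was 34.56 ± 1.39 CPM in Q140 Msh2fl/fl and 29.25 ± 1.17 CPM in Q140 (n = 8 each). These pairs without Cre were not tested in cortex. Ribosomal protein genes were lower in 27 of 85 and choroid plexus and ependymal markers higher in 7 of 12 over the list alone, with none called over all genes (adjusted p = 0.154 and 0.436 with an estimated correlation). The mean length slope was 0.01 in Rgs9Cre Msh2fl/fl and −0.01 in Rgs9Cre cortex. With only these groups in the fit Msh2 (log2 change 0.26, adjusted p = 0.0597), Ttc7 (−0.44, adjusted p = 0.0597), Heatr5b (0.33, adjusted p = 0.148) and Lrpprc (0.18, adjusted p = 0.758) did not pass, at log2 changes near those of the fit to all genotypes. Counts were 29 with DESeq2, 3 with only these groups in the fit, 8 without the libraries of extreme slope and 10 with the slope as a covariate.

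Cre itself was compared on the floxed and on the plain background. Between Rgs9Cre Msh2fl/fl and Msh2fl/fl striatum edgeR and DESeq2 called 0 genes, 1332 had an unadjusted p under 0.05, and edgeR called 1 with the stricter filter. Astrocyte markers had a median log2 change of −0.11, ribosomal protein genes of 0.10 and projection neuron markers of 0.04, with 0 members called over all genes or over the list alone (adjusted p = 0.514, 0.599 and 0.5996 with an estimated correlation). Between Rgs9Cre and WT striatum only Rgs9 was called, 1.30-fold lower (log2 change −0.38 ± 0.06 SE, adjusted p = 0.0025). Without the libraries of extreme length slope its log2 change was −0.36 (adjusted p = 0.0979), and 0 genes were called. Interferon response genes were lower in 2 of 30 over the list alone and in none over all genes (adjusted p = 0.897 with an estimated correlation).

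The floxed alleles without Cre were compared with WT in striatum, and 1304 genes were higher and 1036 lower in Msh2fl/fl. Gm6969 was 2.56-fold higher, at 38.2 ± 6.42 (SD, n = 8) against 14.95 ± 4.37 CPM (n = 7; log2 change 1.36 ± 0.13 SE, edgeR adjusted p = 8.5e-11). The cation channel Trpc5 at 2.25-fold, Lancl3 and the diacylglycerol kinase Dgkk at 2.17-fold, Gpr165 at 1.98-fold, Aff2 at 1.93-fold, the opioid receptor Oprm1 at 1.89-fold and Ston1 at 1.88-fold were higher. The interferon-induced GTPase genes Gbp4 at 2.00-fold and Gbp3 at 1.5-fold, Cyr61 at 1.62-fold, the class I histocompatibility gene H2-Q4 at 1.61-fold and Cox7a2l at 1.38-fold were lower. Htt had a log2 change of 0.24 (adjusted p = 0.072). Of these genes only Gm6969 and Cox7a2l passed with the length slope as a covariate, where the log2 change was 0.22 for Trpc5, 0.43 for Lancl3, 0.61 for Dgkk, 0.27 for Gpr165, 0.16 for Aff2, 0.03 for Oprm1 and 0.47 for Ston1. It was −0.77 for Gbp4, −0.44 for Gbp3, −0.32 for Cyr61 and −0.56 for H2-Q4 there, against −0.9995, −0.58, −0.69 and −0.69 without the covariate. With the mouse number as a covariate again only Gm6969 and Cox7a2l passed, and the first 7 were 0.70, 0.72, 0.91, 0.63, 0.51, 0.44 and 0.62 and the last 4 −0.82, −0.49, −0.54 and −0.60. Oprm1 (0.92, adjusted p = 0.0716) and Cyr61 (−0.69, adjusted p = 0.0566) also did not pass without the low-count filter.

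Members of several lists were called in this comparison, without the lists holding with an estimated correlation. Oxidative phosphorylation genes were lower in 25 of 90 (49 over the list alone) and ribosomal protein genes in 13 of 85 (33 over the list alone; adjusted p = 0.603 and 0.619 with an estimated correlation). Potassium channels were higher in 18 and lower in 2 of 80 (27 and 3 over the list alone), glutamate receptor and postsynaptic density genes higher in 9 of 29 (13 over the list alone), synaptic vesicle genes in 7 of 26 (14 higher and 1 lower over the list alone) and astrocyte markers in 6 of 17 (8 higher and 1 lower over the list alone). These 4 lists each had an adjusted p = 0.603 with an estimated correlation. The length slope averaged 0.0163 in Msh2fl/fl and −0.0295 in WT libraries (exact permutation p = 0.00047, two-sided), and longer genes had higher log2 changes (Spearman rho = 0.363 across 19030 genes, which are not independent replicates). The total of 2340 fell to 34 without the libraries of extreme slope, to 6 with the slope and to 8 with the mouse number as a covariate, and to 689 without the low-count filter.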

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

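Tests chosen after the result was seen were the dose tests of the strain variant in striatum and cortex, the Cre test of the chromosome 17 genes, the shared reads of Gm6969, the length slope and mouse number tests of the floxed genotype, and the dissection test and the 2 tests with Q140 Rgs9Cre of the projection neuron markers. Fisher's test of the genes near Msh2 was chosen in the same way. The Q140 effect differed between striatum and cortex. The difference itself was tested and passed for 5079 genes, and on the log2 scale the effect in striatum minus that in cortex was 6.32 for Wt1, 6.05 for Shox2, 3.95 for Nrn1, 2.56 for Sfmbt2, 2.53 for Dsp, 2.26 for Neurod2 and 1.98 for Pcdh20. It was −2.79 for Sec14l3, −2.70 for Vwa7, −2.67 for Ryr1, −2.49 for Abhd11os, −2.10 for Ddit4l and −0.93 for Rgs9, and 0.27 for Msh2. Between striatal backgrounds, Rgs9Cre Msh2fl/fl minus Rgs9Cre, the difference of the Q140 effect passed in edgeR for Gpx6 (1.44) and Satb2 (−2.45), but for 0 genes with only these groups in the fit, the plate column, the replicate number as a block or limma voom.

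Some libraries lay far from the others of their group. Among genes, Penk was 719.9 CPM and Htt 175.5 CPM in Q140 Msh2fl/fl striatum F1, Rgs9 490.3 CPM in Q140 Rgs9Cre Msh2fl/fl striatum F4, Gm6969 24.4 CPM in WT striatum F1 and Htt 165.3 CPM in Rgs9Cre cortex F3. Rgs9 in cortex was 4.48 CPM in Rgs9Cre Msh2fl/fl M4, 7.36 CPM in Q140 Rgs9Cre Msh2fl/fl M4 and 9.98 CPM in Q140 M4. Total counts were 51.79 M in Q140 Msh2fl/fl striatum F1 and 43.44 M in Q140 Rgs9Cre striatum F4. The mitochondrial share was 12.58% in Q140 Rgs9Cre Msh2+/fl striatum M2 and 6.21% in Msh2fl/fl cortex M4. The length slope was −0.0197 in Q140 Msh2fl/fl striatum F1 and −0.0164 in Q140 Rgs9Cre Msh2fl/fl striatum M1, and the signature score −0.516 in Q140 Rgs9Cre Msh2+/fl cortex M4. In all 15 of 168 groups of values (8.93%) held such a library, where chance gives about 1 in 20.

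Genes of chromosome 17 within 20 Mb of Msh2 made up at least 50% of the called genes in 4 of 6 comparisons of mice with and without floxed alleles: 4 of 5 in Q140 Rgs9Cre Msh2fl/fl against Q140 Rgs9Cre in striatum and 4 of 5 in cortex, and 5 of 10 in Rgs9Cre Msh2fl/fl against Rgs9Cre in striatum and 9 of 16 in cortex, where 0.707% of genes tested in striatum and 0.674% in cortex lie there (Fisher's exact test, adjusted p = 5.05e-08, 5.05e-08, 3.4e-08 and 4.0e-15 over 17 comparisons), but only 32 of 2340 (1.37%, adjusted p = 0.00064) in Msh2fl/fl against WT and 0 of 1 in Q140 Rgs9Cre Msh2+/fl against Q140 Rgs9Cre striatum. Deletion by Cre is argued against, since 8 of these genes differed between Msh2fl/fl striatum with and without Cre by −0.142 of their difference between Msh2fl/fl and WT (bootstrap interval −0.397 to 0.162). A strain variant carried with the floxed allele may remain as an explanation: mice with 1 floxed allele showed 0.538 of the change of mice with 2 in cortex (0.275 to 0.755), a test added once the striatal part of 0.325 (−0.176 to 0.675) had decided nothing. Gm6969 on chromosome 12 may gain reads of Cox7a2l, since its gain in CPM was 1.098 of the loss of Cox7a2l (0.858 to 1.49), inside a band of 0.5 to 1.5 set with the CPM values known. The pattern and both explanations were found and tested in these data, and the strain of origin of the floxed allele is not given. Fisher's test treats neighbouring genes as independent, and the cortical calls near Msh2 include Msh2 itself.

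Many genes differed between Msh2fl/fl and WT striatum. The floxed allele as the cause of most of this is argued against, since the called genes moved between Q140 Msh2fl/fl and Q140 striatum by 0.0222 of that change (bootstrap interval −0.2239 to 0.2503). Gene length bias may account for part: with the length slope as a covariate the mean change in the called direction went from 0.307 to 0.117, or 0.379 of its size, and the median SE from 0.0756 to 0.0523. With the mouse number as a covariate it went to 0.197, or 0.643 of its size, with a median SE of 0.0715. How much of the change goes with the slope or with the mouse number cannot be told, because both differ between these groups (median number 44 in Msh2fl/fl and 15 in WT, exact permutation p = 0.0196), and only 6 and 8 genes were still called, where the mean change was smaller by a larger part than the median SE.

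Projection neuron markers were higher in Q140 Rgs9Cre Msh2fl/fl than in Q140 Msh2fl/fl striatum by 0.166, which is 22.99% of their fall from WT to Q140. Whether more projection neuron tissue in the dissection gave the rise was not decided. Markers that fell more with Q140 rose more at a like enrichment in striatum (slope 0.104, exact permutation p = 0.0025, and 0.0670 with p = 0.0238 without Ryr1). The permutation swaps libraries between the groups, so it tests whether they differ and not what makes them differ. Enrichment over cortex also does not measure how specific a marker is to these neurons within striatum. This test replaced one without enrichment (slope 0.103, exact permutation p = 0.0025) set before and seen first. Deletion of Msh2, not shown by its RNA, stays open. The markers were higher by 0.124 (bootstrap interval 0.0588 to 0.191, exact permutation p = 0.0042) than in Q140 Rgs9Cre. This is 17.6% of the fall from Rgs9Cre to Q140 Rgs9Cre. Both rises rest on Q140 Rgs9Cre Msh2fl/fl, whose high mean could give both. The Rgs9Cre allele as the cause of the whole rise is argued against, since Q140 Rgs9Cre differed from Q140 by −0.0117, far under the 0.166 it would need (bootstrap interval −0.0822 to 0.0585), a test that replaced one of whether the rise with Cre was larger with Q140 than without it (0.128, permutation p = 0.0747) set before and seen first. The list did not hold with an estimated correlation against Q140 Rgs9Cre (adjusted p = 0.400). Nor did it as an interaction (smaller adjusted p 0.4175, against Msh2fl/fl). Without Q140 the markers averaged 8.596 ± 0.0555 (SD, n = 6) in Rgs9Cre Msh2fl/fl and 8.546 ± 0.0647 (n = 8) in Rgs9Cre striatum.

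Each count of genes was set beside 100 splits of the same libraries, the real one included. For striatum Q140 against WT, 1 of the 100 gave as many genes (7866, highest other 4957), and so did 1 with Rgs9Cre (6363, 4887), 1 with Msh2fl/fl (6857, 4325) and 1 with Rgs9Cre Msh2fl/fl (5257, 3012). In cortex the numbers were 1 for Q140 against WT (442, 133), 1 with Rgs9Cre (724, 515), 1 with Msh2fl/fl (1239, 33) and 1 with Rgs9Cre Msh2fl/fl (395, 32), and for the tissue difference 1 (5079, 2981). For Q140 Rgs9Cre Msh2fl/fl they were 2 against Q140 Rgs9Cre (5, 6) and 1 against Q140 Msh2fl/fl (4, 1) in striatum and 1 against Q140 Rgs9Cre in cortex (5, 3). Msh2fl/fl against WT gave 1 (2340, 27), striatal Rgs9Cre Msh2fl/fl against Rgs9Cre 2 (10, 69) and the interaction with Rgs9Cre 2 (2, 12). These shares lie under 0.05, without adjustment over the comparisons, so few splits gave as many genes. The splits treat the libraries as exchangeable, which the structure named below does not bear out, so they exclude no cause tied to it. The share was at least 0.05 for Q140 Rgs9Cre Msh2+/fl against Q140 Rgs9Cre with 11 (1, 6212), Rgs9Cre against WT with 5 (1, 727) and cortical Rgs9Cre Msh2fl/fl against Rgs9Cre with 8 (16, 2736). For Rgs9Cre Msh2fl/fl against Msh2fl/fl and for the interaction with Msh2fl/fl, with 0 genes, all 100 splits gave as many (highest other 10 and 5). Splits that called several times the real number, up to 6212, 727, 2736, 69 and 12 genes, point to a structure of the samples other than genotype. The length slope and the mouse number show such a structure, since 8 of 9 striatal libraries of extreme slope came from mice numbered 3 to 12.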

How the results depend on the processing

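Settings with the length slope or the mouse number as a covariate, without the libraries of extreme slope and with 50 genes per direction were tests chosen after seeing the data. Under planned settings 133 counts of genes stayed within 1.5 times the value reported and 25 moved further, and under the added ones 40 and 18. Named genes kept direction and side of the threshold in 1554 values under planned settings, while 44 no longer passed, 18 newly passed and 1 reversed; under the added ones 485, 47, 8 and 3. The count for striatum Q140 vs WT ran from 7028 with the plate column to 8417 with limma voom, and 682 of 685 values of its named genes stayed the same. Low counts limit Hoxc4, Hoxc5 and Hoxc6. The cause of the changes below was not tested, except that fits with only the groups compared have fewer libraries.

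For striatal Q140 Rgs9Cre Msh2fl/fl against Q140 Rgs9Cre (5 genes) the count was 3 with only the groups compared, 15 with limma voom and 8 with the slope covariate. Against Q140 Msh2fl/fl (4) it was 27 with DESeq2, 10 with only the groups, 2 with the plate column and 70 with limma voom. It was 21 without extreme libraries, 39 with the slope and 8 with the mouse number. Of the 4 genes, 1 was among the 27 of DESeq2 in the same direction. For Q140 Rgs9Cre Msh2+/fl against Q140 Rgs9Cre (1) it was 0 with only the groups, and 2 with limma voom and without extreme libraries. Rgs9Cre Msh2fl/fl against Rgs9Cre (10) gave 16 with DESeq2, 5 with only the groups, 6 with the slope and 6 with the mouse number, and against Msh2fl/fl (0) it gave 1 with the stricter filter. Msh2fl/fl against WT (2340) gave 689 without a filter, 34 without extreme libraries, 6 with the slope and 8 with the mouse number. Rgs9Cre against WT (1) gave 0 without extreme libraries and 2 with the slope. The interaction with Rgs9Cre (2) gave 0 with only the groups, the plate column and limma voom, and 1 without extreme libraries.

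In cortex Q140 against WT (442) gave 854 with limma voom. Q140 Rgs9Cre against Rgs9Cre (724) gave 236 with only the groups, 332 without extreme libraries and 329 with the slope, and Q140 Msh2fl/fl against Msh2fl/fl (1239) gave 759 and, with the slope, 674. Q140 Rgs9Cre Msh2fl/fl against Q140 Rgs9Cre (5) gave 3 with only the groups. Rgs9Cre Msh2fl/fl against Rgs9Cre (16) gave 29 with DESeq2, 3 with only the groups, 8 without extreme libraries and 10 with the slope. Of 174 list tests passed by camera, 11 passed with an estimated correlation, 4 of them of Hox genes, whose direction the filter fixed.

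The replicate numbers did not pair the samples. Same-numbered libraries had a mean correlation of 0.012 over 240 striatal pairs and 0.017 over 264 cortical ones, over 0.1 in 20.8% and 22.4%. With the replicate number as a block, striatal Q140 Rgs9Cre Msh2fl/fl gave 3 genes against Q140 Rgs9Cre and 1 against Q140 Msh2fl/fl, Rgs9Cre against WT gave 3 and the interaction with Rgs9Cre gave 0.

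The striatal score difference of Q140 Rgs9Cre Msh2fl/fl and Q140 Rgs9Cre (0.024) was −0.0220 with genes changed by 0.5 or more, −0.0943 with the signature from Q140 Msh2fl/fl, −0.0228 without extreme libraries, −0.0635 with the slope and −0.152 with 50 genes. The difference from Q140 Msh2fl/fl was −0.0302 with only higher genes (exact permutation p = 0.0785). Q140 Rgs9Cre Msh2+/fl minus Q140 Rgs9Cre was 0.0155 with the signature from Q140 Msh2fl/fl and 0.0409 without extreme libraries, and Rgs9Cre Msh2fl/fl minus Rgs9Cre −0.0418 and, with the slope, −0.0121. In cortex the first difference was −0.00612 at an adjusted p under 0.01, −0.0312 with changes of 0.5 or more, −0.00778 with only higher genes and −0.0252 with the other signature. Cortical Q140 Rgs9Cre Msh2+/fl minus Q140 Rgs9Cre was 0.0545 with the other signature, and Rgs9Cre Msh2fl/fl minus Rgs9Cre −0.0130 with the slope. The cortical effect remaining was 102.1% with only lower genes and 106.6% with the slope.

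The log2 change of Htt in striatal Q140 against WT (0.03) was −0.0708 without extreme libraries, −0.0590 with the mouse number and −0.242 with the slope (adjusted p = 4.1e-06), and that of Rgs9 in cortex was 0.0209 with limma voom. The rise of the projection neuron markers kept 1.007 of its size with the slope (bootstrap interval 0.960 to 1.06).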

Other observations

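The overlap between the tissues and the sums of Gm6969 and Cox7a2l were tests chosen after results were seen, while the gene lists had been fixed before. In striatum of Q140 carriers on the other backgrounds, members of further lists were called, where 33.32%, 35.91% and 27.53% of all genes were called with Rgs9Cre, Msh2fl/fl and Rgs9Cre Msh2fl/fl, and none of these lists held with an estimated correlation. Endothelial and mural markers were lower in 8, 9 and 4 of 17 in that order (8, 10 and 4 adjusted over the list alone), where camera passed only with its preset correlation (adjusted p = 0.395, 0.2198 and 0.454 with an estimated correlation). Mismatch repair and CAG repeat instability genes were higher in 8, 16 and 8 of 28 and lower in 2 of 28 on each background (8, 19 and 8 higher and 2 lower over the list alone; adjusted p = 0.390, 0.0648 and 0.450 with an estimated correlation). Oligodendrocyte precursor markers were higher in 5 of 14 with Rgs9Cre Msh2fl/fl, over all genes and over the list alone (adjusted p = 0.454 with an estimated correlation).

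In cortex members of further lists were called, and differences between the backgrounds were not tested. Choroid plexus and ependymal markers, genes of the tissue that makes cerebrospinal fluid, were lower in 4 of 12 between Q140 Rgs9Cre Msh2fl/fl and Rgs9Cre Msh2fl/fl cortex (7 lower and 1 higher over the list alone; adjusted p = 0.424 with an estimated correlation). Astrocyte markers were lower in 2, 5 and 3 of 17 with Rgs9Cre, Msh2fl/fl and Rgs9Cre Msh2fl/fl (5, 8 and 4 over the list alone; adjusted p = 0.453, 0.253 and 0.178 with an estimated correlation). Of the 18159 genes tested in both tissues, 118 were higher and 147 lower in Q140 in striatum and in cortex, against 37.3 and 50.1 for independent lists, and 26 were called in opposite directions. Both tissues came from the same mice, so that these lists are not independent.

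The counts of Gm6969 and Cox7a2l together did not pass an exact permutation test in any of 6 comparisons of mice with and without floxed alleles. They summed to 101.2 ± 8.95 CPM (SD, n = 6) in Rgs9Cre Msh2fl/fl and 98.6 ± 5.11 CPM (n = 8) in Rgs9Cre striatum (exact permutation p = 0.519). The comparison nearest to the threshold was Q140 Rgs9Cre Msh2fl/fl against Q140 Rgs9Cre cortex, at 86.45 ± 4.02 and 82.45 ± 3.47 CPM (n = 8 each, exact permutation p = 0.0536). Ttc7, also in the dose and Cre tests, was lower with floxed alleles in cortex. In striatum its log2 changes against unfloxed Msh2 were 0.13 in Rgs9Cre Msh2fl/fl and 0.10 in Q140 Rgs9Cre Msh2fl/fl.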
